A study of Homo sapiens with 6 samples.

How the data were processed

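Gene expression was measured by RNA sequencing in 6 libraries of KYSE510, an established cell line of oesophageal squamous cell carcinoma grown in medium with serum. Per the labels' protocols, total RNA was taken up in Trizol, poly(A) RNA was selected on oligo(dT) beads, fragmented and copied with random primers, and single-stranded circular DNA libraries were made after PCR. Per the submitters' processing notes, HISAT2, StringTie and DESeq2 were used with the GRCh38 build; their versions, the step each served, the annotation release, the read counter and its strand setting are not given in the sources used here. The deposited values are raw counts per gene, whole numbers for 62700 Ensembl gene IDs in each of the 6 libraries, with no normalisation by the authors. Each count column carried the name in 1 sample's description, and 0 columns were left unmatched.

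Because strand use is not stated, reads from the stretch that a gene shares with an overlapping or antisense gene could not be told apart, and near-identical paralogs can share reads. Symbols were found for 62700 of the 62700 IDs. Positions, gene types, GC content and transcript length came from GENCODE 29 on GRCh38, a different release from that of the count table, which held 58207 of the IDs and covered 95.3% of the tested genes for GC content and length. All 37 genes of the mitochondrial chromosome in that annotation were listed at 0 in the 6 libraries, so mitochondrially encoded mRNAs could not be tested. Library totals ran from 31394687 to 41103220 counts. Some other genes were also listed at 0 in every library, and whether the counting left them out is not given in the sources used here, so a 0 is reported only as listed. Intervals of fold changes come from the standard error of the fit and cover the spread between samples. The labels call the samples biological replicates without saying how cultures were separated, so p-values measure the spread between these samples. Replicates were compared by chi-square over genes, and every pair within a group differed by more than sampling noise (6.67 to 21.6 per gene), so none was taken as a copy of another.

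The test was edgeR's quasi-likelihood test (edgeR 4.0.16 in R 4.3.3) on the deposited counts of 3 shControl and 3 shRNH1 libraries, with TMM normalisation, filterByExpr by group, no covariate, and Benjamini-Hochberg adjustment over 19682 genes at a threshold of 0.05. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. CPM are normalised by TMM and given as mean ± SD. CPM of the targeted genes were also compared by an exact two-sided permutation test, whose smallest possible p for 3 against 3 is 0.1. The 30 gene lists were tested with limma's camera (limma 3.58.1) on limma-voom values with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 28 lists with at least 5 tested members, besides an estimated correlation and fry. The lists covered R-loop and RNase H factors, interferon-stimulated genes, nucleic acid sensing, NF-kB targets, p53 targets, homologous recombination, DNA replication, mitosis, histones, the ATF4 response, endoplasmic reticulum chaperones, squamous differentiation, basal squamous genes, mesenchymal genes, mitochondrially encoded mRNAs, mitochondrial DNA maintenance, oxidative phosphorylation, cholesterol synthesis, hypoxia and glycolysis, NRF2 targets, ribosomal proteins, ribosome biogenesis and MYC targets, MHC class I, immediate early genes, heat shock, abundant long noncoding RNAs, and markers of fibroblasts, leukocytes, endothelium and simple epithelium.

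The test, the lists, a first set of alternatives and the rule for named genes were chosen before the data were examined. That rule took RNASEH1 and RNH1, and the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 CPM of at least 2 and no overlap between groups. Genes with only a clone or locus name, XIST and Y-linked genes were left out of that ranking. The rule also took, per list, up to 4 members past the threshold with the smallest adjusted p, or 6 for the R-loop and interferon lists. For the MHC class I list, 1 gene that the rule took is not reported here. That first set held other size factors, library size alone, DESeq2 1.42.0, limma-voom, no filter and a stricter filter (CPM of at least 1 in at least 3 libraries), a replicate block, an offset for GC content and length, protein-coding genes alone, and each replicate left out. Added after seeing the data were an offset for expression level, thinning of all libraries to the smallest total, camera without RNASEH1, camera with other size factors and offsets, and lists of YAP/TEAD targets, ERK output genes and interferon genes. The offsets were smooth trends fitted with splines of 5 degrees of freedom by robust regression (MASS 7.3.60.0.1).

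On data simulated from these libraries with 200 changed genes, for shRNH1 against shControl, edgeR ran on 18847 genes and recovered 67.2% of 1.5-fold, 97.0% of 2-fold and 100% of 4-fold changes, with 9.74% of its calls false. DESeq2 recovered 67.2%, 95.5% and 100% over 19682 genes with 11.2% of calls false, and limma-voom 65.7%, 97.0% and 100% over 18847 genes with 6.91% false. The changed genes were drawn only from genes with a mean shControl CPM above 1, so recovery of lower genes was not measured. Far fewer genes were changed than passed in the real data, which can alter the adjusted threshold. The simulated genes were drawn independently. In a separate simulation, in which only a list of randomly drawn genes was shifted down, camera called that list lower. There it called 0 of 28 unshifted lists at the adjusted threshold. Because genes were drawn independently there too, this does not measure its false calls for lists whose members vary together.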

Results

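RNA of KYSE510 cells, a line of oesophageal squamous cell carcinoma, was sequenced in a knockdown model of induced R-loops, structures in which RNA pairs with DNA and displaces the other strand. The 6 libraries formed 2 groups, 3 of cells with a control shRNA (shControl) and 3 of cells with an shRNA against the gene that the labels name RNH1 (shRNH1). Total counts were 40225486, 41103220 and 40461210 in the shControl libraries and 33420444, 33421217 and 31394687 in the shRNH1 libraries. The 10 most abundant genes took 5.97% to 6.996% of the counts of a library. Pearson's r of log2 CPM across genes, which are not independent replicates, was 0.987 to 0.992 within groups and 0.976 to 0.979 between groups, and the first principal component, with 52.9% of the variance, separated the groups.

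The first question was which gene the knockdown had lowered, because RNH1 is also the approved symbol of the ribonuclease inhibitor. RNASEH1 (ENSG00000171865; GRCh38 chromosome 2, 3544793 to 3558616, minus strand), which encodes the ribonuclease that cleaves RNA in RNA:DNA hybrids, fell in the shRNH1 libraries. Its counts were 1357, 1344 and 1015 in shControl and 251, 247 and 232 in shRNH1, or 31.6 ± 3.73 and 7.16 ± 0.213 CPM (SD, n = 3 each). The log2 fold change was -2.14 (SE 0.116; adjusted p = 1.61e-13, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), which left 22.6% of the control level (95% interval 19.2% to 26.7%). The exact two-sided permutation test of the CPM gave p = 0.1, the smallest that 3 against 3 allows. The ribonuclease inhibitor gene RNH1 (ENSG00000023191; chromosome 11, 494512 to 507300, minus strand) measured 546 ± 97.4 CPM in shControl and 478 ± 45.5 in shRNH1 (SD, n = 3 each), and the groups overlapped. Its log2 fold change of -0.19 (SE 0.112) did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (adjusted p = 0.221), and the exact permutation test gave p = 0.4. It passed with an offset for GC content and length (-0.23, adjusted p = 0.0426, same test), but was -0.07 with library size alone, 0.05 with an offset for expression level, -0.04 without shControl replicate 3 and -0.30 without shControl replicate 2, and passed in none of these. The divergent transcript RNASEH1-DT (chromosome 2, 3558492 to 3561745, plus strand), which overlaps the 5' end of RNASEH1, had a log2 fold change of -0.04 (SE 0.161; adjusted p = 0.888, same test).

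**Figure D1:**
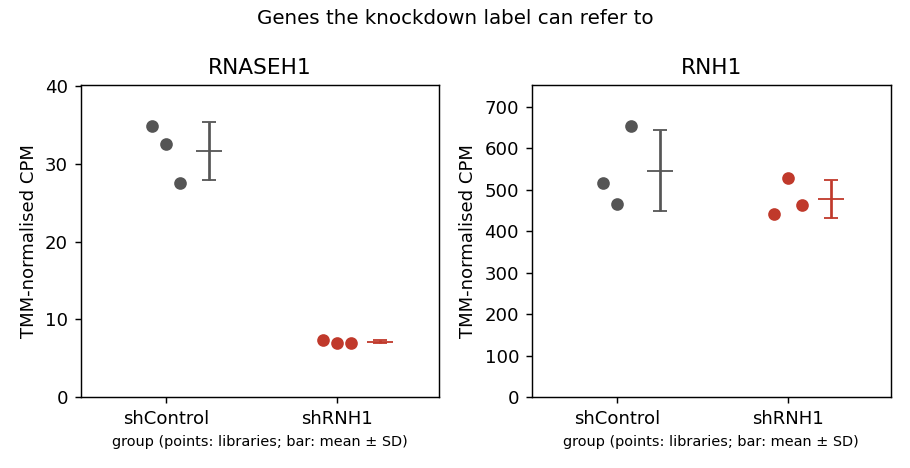
TMM-normalised CPM of RNASEH1 and RNH1 in each of the 3 shControl (grey) and 3 shRNH1 (red) libraries, with the group mean and SD as bars beside the points and both axes starting at 0. RNASEH1 averaged 31.6 CPM in shControl and 7.16 CPM in shRNH1, whereas the RNH1 values of the groups overlapped.

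The second question was what else differed between shRNH1 and shControl cells. Among the genes that the naming rule admits, at a mean log2 CPM of at least 2, the largest rises were in CA9 (ENSG00000107159; chromosome 9, 35673856 to 35681159), a carbonic anhydrase induced by hypoxia, from 1.70 ± 0.124 to 28.0 ± 1.41 CPM, and in ALPI (ENSG00000163295; chromosome 2, 232456123 to 232460032), the intestinal alkaline phosphatase, from 12.5 ± 1.89 to 204 ± 17.6 CPM (SD, n = 3 each). These were 16.4-fold and 16.3-fold changes. The interferon-inducible gene IFI27 rose 15.3-fold from 0.557 ± 0.202 to 8.63 ± 0.573 CPM. The transcription factor genes ATOH8, DLX3 and MEOX1 rose by log2 fold changes of 3.59, 3.27 and 2.93. MYH14 (3.21), a nonmuscle myosin heavy chain, TNFRSF18 (2.85), the amino acid transporter gene SLC7A8 (2.61) and the growth factor gene IGF2 (2.57) completed the 10 largest rises. Adjusted p of these 10 genes lay between 8.81e-19 and 1.14e-10 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). ALPI shares sequence with ALPP and ALPG, which rose by less (0.73 and 1.52), so its counts carry some uncertainty.

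Among the 10 largest falls by the same rule, at a mean log2 CPM of at least 2, THBS1 (ENSG00000137801; chromosome 15, 39581079 to 39599466), encoding thrombospondin, fell from 167 ± 4.58 to 27.3 ± 0.874 CPM, and SPARC (ENSG00000113140; chromosome 5, 151661096 to 151687165), a matrix glycoprotein, fell from 244 ± 14.2 to 41.7 ± 2.80 CPM (SD, n = 3 each). CCN1, a matricellular protein, fell from 279 ± 33.5 to 53.1 ± 1.82 CPM. Tissue factor F3 (-2.46), the ligand gene NRG1 (-2.26), CCRL2 (-2.25), NNMT (-2.23), MARCHF4 (-2.16), RNASEH1 (-2.14) and the keratin gene KRT6A (-2.13) also fell. The adjusted p of these genes lay between 6.17e-17 and 3.83e-11 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The KRT6A paralogs KRT6B and KRT6C had 0 to 5 counts per library.

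Over all 19682 genes tested, 5424 (27.6%) passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3006 higher and 2418 lower in shRNH1. With protein-coding genes alone 4971 of 13352 passed. Counts of list members below are to be read against these shares. Of the 5424 genes, some changed by more than others. An absolute log2 fold change of at least 1 was reached by 1234 of them, 948 higher and 286 lower. Groups did not overlap for 7868 genes (39.98%, against 10% by chance), and 7333 genes had an unadjusted p below the threshold. The median log2 fold change was 0.016, or 0.127 with library size alone, where 4065 genes were higher and 1433 lower (73.9% higher, against 55.4% with TMM). By expression level, from the lowest to the highest of 5 bins of genes, median log2 fold changes were 0.079, 0.073, 0.106, 0.0005 and -0.097, so the abundant genes lay lower, and with an offset for this trend 3505 genes were higher and 1711 lower.

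**Figure D2:**
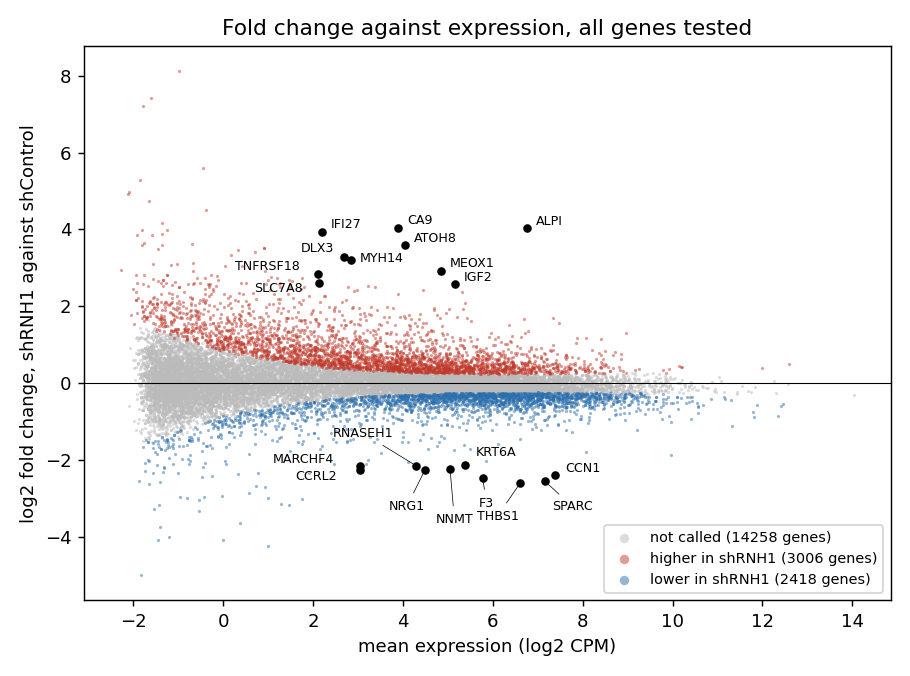
Log2 fold change of shRNH1 against shControl (vertical axis) by mean log2 CPM (horizontal axis) for the 19682 genes tested. Red points mark the 3006 genes higher and blue points the 2418 genes lower in shRNH1, and grey points did not pass the test. Black points name the 10 largest rises and falls by the naming rule, at a mean log2 CPM of at least 2.

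Most interferon-stimulated genes rose. Of 44 tested members, 35 rose and 0 fell (38 and 0 when adjusted over the list alone) by edgeR's test, with a median log2 fold change of 0.62. At an unadjusted p below the threshold 0 members were lower too, and DESeq2 and limma-voom called 0 lower. Besides IFI27, OAS1 (1.84), OAS2 (1.74) and OASL (1.19), of the oligoadenylate synthetase family that senses double-stranded RNA, rose, as did IFI6 (1.91) and the ISG15 ligase gene HERC5 (1.32). OASL went from 163 ± 4.55 to 372 ± 43.2 CPM (SD, n = 3 each). Limma's camera gave this list an adjusted p of 6.50e-18, and an adjusted p = 0.0783 with an estimated correlation. The MHC class I antigen presentation list had 7 members higher and 1 lower of 17 tested, among them HLA-F (1.38), HLA-B (0.82) and B2M (0.74), the shared light chain. Camera gave an adjusted p of 0.00765 for it, and an adjusted p = 0.260 with an estimated correlation. The median of that list was 0.12, but 0.07 without shRNH1 replicate 1, 0.19 without shRNH1 replicate 2, 0.23 with library size alone and 0.27 with the expression level offset. HLA genes are polymorphic relatives whose reads can be shared. Among 15 tested members of the nucleic acid sensing list, 3 rose and 4 fell. DHX58 (1.05) and EIF2AK2 (0.34), an RNA-activated kinase, rose, whereas PQBP1 (-0.53) and the kinase gene IKBKE (-0.47) fell, and camera did not call the list (adjusted p = 0.768). Leukocyte markers, which would report immune cells, had 2 of 14 members at a testable level, and 0 passed edgeR's test, 0 had an unadjusted p below the threshold, and limma-voom called 0 and DESeq2, which tests more low genes, 1. CSF1R, the one with the smaller p, had a log2 fold change of 0.25.

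**Figure D3:**
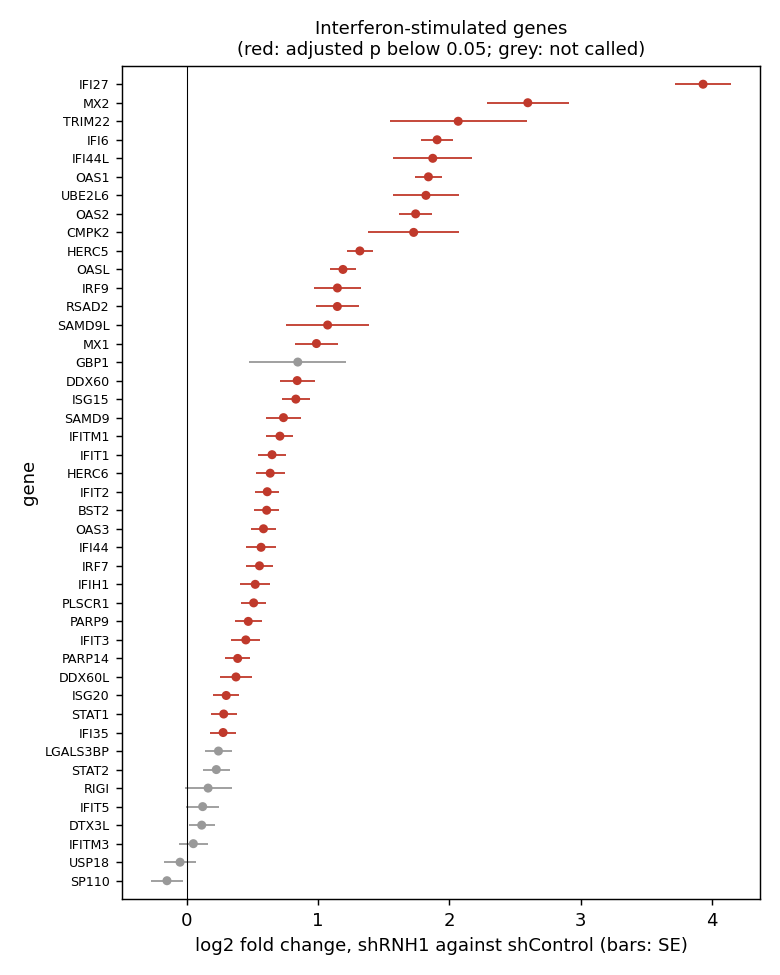
Log2 fold change of shRNH1 against shControl with its SE (horizontal bars) for the 44 tested interferon-stimulated genes, ordered by size. The 35 red genes passed the adjusted threshold and all of these lie above 0, with IFI27 at 3.93, and grey genes did not pass.

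Hypoxia and glycolysis genes had 16 members higher and 5 lower of 32, with a median log2 fold change of 0.26. CA9, NDRG1 (1.57), the enolase gene ENO2 (1.96) and the aldolase gene ALDOC (1.79), the members with the smallest p, rose far more than that median. Camera gave the list an adjusted p = 4.38e-04, and an adjusted p = 0.245 with an estimated correlation.

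In the ribosome biogenesis and MYC target list 27 of 34 members fell and 1 rose, with a median log2 fold change of -0.43 (camera adjusted p = 1.83e-13, and adjusted p = 0.245 with an estimated correlation). NOB1 (-0.77), MYBBP1A (-0.75), RRP12 (-0.63) and the polyamine enzyme gene ODC1 (-0.65) were the members with the smallest p. MYBBP1A went from 1058 ± 100 to 629 ± 6.82 CPM (SD, n = 3 each). With the expression level offset 18 members were lower, at a median of -0.28. The cytosolic ribosomal protein list moved less, with 14 of 69 members lower, 2 higher and a median of -0.08 (camera adjusted p = 0.00765, and adjusted p = 0.995 with an estimated correlation). RPL37 (-0.43), RPL12 (-0.41), RPS29 (-0.47) and RPL23A (-0.39) fell. The share of the ribosomal protein list that passed lay below the 27.6% over all genes tested. The median of that list turned to 0.03 with library size alone, to 0.13 with the expression level offset and to 0.03 without shRNH1 replicate 2, and the list was also not called without shControl replicate 1 (adjusted p = 0.0683). RPL12 (-0.20) and RPL23A (-0.22) did not pass with the expression level offset.

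Of 30 mesenchymal genes, 18 fell and 4 rose, with THBS1, SPARC, CCN1 and CCN2 (-2.33) in front (camera adjusted p = 1.30e-07, and adjusted p = 0.245 with an estimated correlation). Fibroblast markers did not move one way, since MFAP5 (-2.04) and PDGFRB (-0.91) fell whereas the collagen gene COL1A1 (0.98) and FBLN1 (0.79) rose, of 5 tested. Immediate early genes had 12 lower and 5 higher of 25, with falls in FOSL1 (-1.44), SPRY4 (-0.96), IER3 (-0.95) and PHLDA1 (-0.98) (camera adjusted p = 9.76e-04, and adjusted p = 0.646 with an estimated correlation). NF-kB targets had 11 lower and 5 higher of 26. IL11 (-1.54) and the NF-kB subunit genes NFKB2 (-1.08) and RELB (-1.05) fell, whereas the chemokine gene CCL5 (1.68) rose (camera adjusted p = 0.00678, and adjusted p = 0.646 with an estimated correlation).

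Among heat shock genes 9 of 19 fell and 0 rose by edgeR's test, with 0 higher at an unadjusted p below the threshold and 0 called higher by DESeq2 or limma-voom. BAG3 (-0.54), the regulator gene HSF1 (-0.49), HSPA8 (-0.41) and DNAJB6 (-0.34) were the members with the smallest p (camera adjusted p = 4.38e-04, and adjusted p = 0.245 with an estimated correlation). With the expression level offset the heat shock list was not called (median -0.07 against -0.24, adjusted p = 0.217), and neither HSPA8 (-0.12, adjusted p = 0.391) nor DNAJB6 (-0.20, adjusted p = 0.1005) passed edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. DNAJB6 also missed it with library size alone (-0.22, adjusted p = 0.0612), and HSPA8 without shControl replicate 1 (-0.37, adjusted p = 0.0514). Mitosis genes had 7 lower and 2 higher of 36, with falls in CDC20 (-0.65), the cyclin gene CCNB1 (-0.43) and the kinase genes AURKB (-0.37) and AURKA (-0.37) (camera adjusted p = 0.00972, and adjusted p = 0.871 with an estimated correlation). The share of mitosis genes that passed lay below the 27.6% over all genes tested, and the median of the mitosis list was -0.13. The list was not called without shRNH1 replicate 2 (median -0.08, adjusted p = 0.168), nor with library size alone (median -0.03), and its median was 0.006 with the expression level offset, where AURKB (-0.21) and AURKA (-0.22) did not pass. Genes of mitochondrial DNA maintenance and transcription, a list that holds RNASEH1, had 11 of 26 lower, among them TFB2M (-0.60), ELAC2 (-0.48) and the helicase gene TWNK (-0.49). Camera gave it an adjusted p of 3.68e-05 with RNASEH1 and 3.59e-04 without it, and an adjusted p = 0.260 with an estimated correlation. Mitochondrially encoded mRNAs were listed at 0 in every library.

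R-loop and RNase H factors other than RNASEH1 moved little. Of 29 members 8 fell, RNASEH1 included, and 1 rose, with a median of -0.11. The helicase genes DDX41 (-0.44) and DDX21 (-0.40) and the mRNA export factor genes ALYREF (-0.44) and THOC5 (-0.35) fell, and THOC6 (0.41) of the same export complex as THOC5 rose. Camera called the list with RNASEH1 (adjusted p = 0.0193) but not without it (adjusted p = 0.0782), and gave an adjusted p = 0.646 with an estimated correlation. The list was not called without shRNH1 replicate 2 (median -0.05, adjusted p = 0.0705). Its median was -0.07 without shControl replicate 2, near 0 with library size alone (-0.002) and 0.01 with the expression level offset. With the expression level offset DDX21 (-0.21) and THOC5 (-0.24) did not pass, nor did THOC5 with library size alone (-0.24). DDX21 did not pass without shControl replicate 1 (-0.31, adjusted p = 0.0579) and THOC5 not without shRNH1 replicate 2 (-0.24, adjusted p = 0.0626; edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment for both).

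Targets of p53 did not move one way. Of 25 tested, SESN2 (0.64), BBC3 (0.68) and others made 4 higher, and AEN (-0.66), PLK3 (-0.64) and others made 4 lower (camera adjusted p = 0.985). DNA replication genes had 6 higher and 4 lower of 42, homologous recombination and Fanconi anaemia genes 4 and 2 of 38, and histone genes 2 and 2 of 26. The ATF4 list had 7 higher and 6 lower of 30, endoplasmic reticulum chaperones 1 and 3 of 24, NRF2 targets 6 and 7 of 30, cholesterol synthesis 7 and 2 of 25, and nuclear oxidative phosphorylation 4 and 2 of 43. Squamous differentiation genes had 8 higher and 7 lower of 22, basal squamous genes 7 and 10 of 24, and abundant long noncoding RNAs 2 and 4 of 11. Simple epithelial markers had 7 higher and 4 lower of 16, with rises in the hepatic and intestinal regulator gene HNF4A (1.34) and the villin gene VIL1 (2.32) and falls in the keratin genes KRT7 (-1.11) and KRT18 (-0.92). Endothelial markers had 3 higher of 6, namely ESAM (1.26), EGFL7 (0.36) and PECAM1 (0.51). EGFL7 did not pass without shControl replicate 1 (0.33) or 2 (0.29), nor PECAM1 without shControl replicate 2 (0.47) or 3 (0.45) or shRNH1 replicate 1 (0.32), nor by DESeq2 (0.48) or with the expression level offset (0.42). Camera did not call the histone, basal squamous or cholesterol lists, with adjusted p of 0.276, 0.0934 and 0.276. Without shControl replicate 2 it called histones (median -0.22, adjusted p = 5.45e-04) and basal squamous genes (-0.11, adjusted p = 0.0232), the latter also with the replicate block (adjusted p = 0.0410), and with the expression level offset cholesterol synthesis (0.20, adjusted p = 0.0119). Median, mean and test differed in sign for DNA replication, ATF4, chaperone, NRF2, long noncoding RNA and fibroblast lists.

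**Figure D4:**
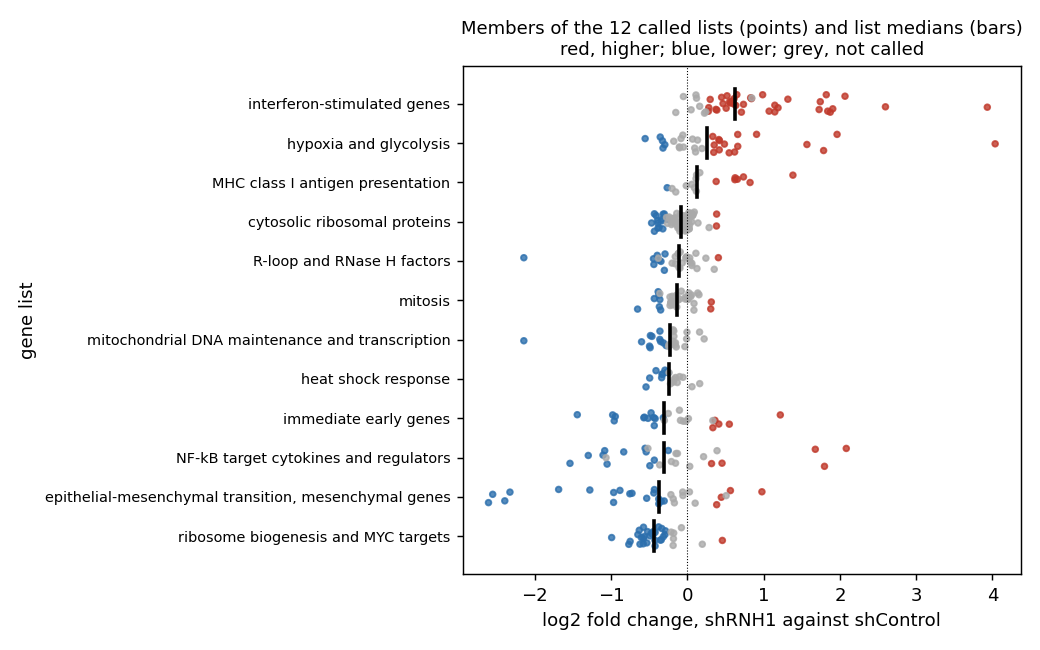
Log2 fold change of each tested member (points) and the median (black bars) of the 12 gene lists that camera called with a preset correlation. Red members rose, blue members fell and grey members did not pass the test, and medians run from -0.43 for ribosome biogenesis and MYC targets to 0.62 for interferon-stimulated genes. The median of the R-loop and mitosis lists turns above 0 with the expression level offset, and that of the ribosomal proteins also with library size alone.

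Camera with a preset correlation called 12 of 28 lists, 3 higher and 9 lower, fry called 7 by direction, and with an estimated correlation camera called 0 (smallest adjusted p 0.0783), with 5 at an unadjusted p below the threshold. The other splits of the 6 libraries into 3 and 3 called 6 to 16 lists by camera with the preset correlation and 0 genes by edgeR's test, with 139 to 713 genes at an unadjusted p below the threshold. The number of lists called did not set the real groups apart from those splits. Each of those splits joined libraries of both groups in unequal shares, so it kept part of the real difference and was not free of signal.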

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

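The offset for expression level, thinning to equal depth, camera without RNASEH1 and the lists under other size factors or the GC offset were chosen after the data had been seen; the other alternatives were not. Over all alternatives 4150 to 6562 genes passed the test, and none of the 5424 genes passed in the opposite direction in any of them. RNASEH1 stayed lower in each, from -2.23 without shControl replicate 3 to -2.04 with library size alone. RNH1 passed only with the GC content and length offset (-0.23) and with the replicate block plus that offset (-0.22), and ranged from -0.30 without shControl replicate 2 to 0.05 with the expression level offset. Library size alone gave 1433 lower genes, a shift of the scale shown by the median, and the stricter filter gave 809 genes with an absolute log2 fold change of at least 1, because fewer low genes were tested (14631). The number of lists called was 0 with an estimated correlation and 7 with fry. Lists called only in an alternative were histones (without shControl replicate 2, median -0.22), basal squamous genes (replicate block, -0.08; without shControl replicate 2, -0.11) and cholesterol synthesis (expression level offset, 0.20). With the expression level offset the heat shock list was lost (median -0.07) and the medians of the R-loop (0.0138), mitosis (0.00555) and ribosomal protein (0.13) lists were above 0; the ribosomal protein median was also 0.0318 with library size alone and ranged from -0.146 to 0.0297 as libraries were left out, the highest without shRNH1 replicate 2. Other medians of called lists that moved by over 1.5 times were those of MHC class I (0.07 without shRNH1 replicate 1 to 0.27 with the expression level offset), of the R-loop and mitosis lists without shRNH1 replicate 2 (-0.05 and -0.08), of NF-kB targets (-0.19), immediate early genes (-0.19), heat shock (-0.13) and mitochondrial DNA maintenance (-0.11) with library size alone, and of immediate early genes (-0.16), hypoxia and glycolysis (0.41) and ribosome biogenesis (-0.28) with the expression level offset. The R-loop and mitosis medians also moved that far with library size alone (-0.002 and -0.03), as did the R-loop median without shControl replicate 2 (-0.07). The cause of the list changes was not tested. Of the 84 other named genes, 83 passed and 73 of these kept direction and threshold in every alternative; the changes were weaker calls in 20 cases, of DDX21, THOC5, AURKB, AURKA, RPL12, RPL23A, HSPA8, DNAJB6, EGFL7 and PECAM1. The replicate numbers do not pair the samples: deviations of same-numbered libraries correlated at 0.045, 0.056 and -0.049, and only the libraries numbered 2 matched their own number best. The replicate block gave 5094 genes, 2938 higher and 2156 lower. Depth limits the low genes: 19682 of 36838 genes with a read were tested.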

Other observations

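The lists of YAP/TEAD targets, ERK output and interferon genes, the ERK and fibroblast tests, the expression level offset, the thinning and the single genes named next were chosen only after the data had been seen. Other single genes moved too. Of the genes named next, MYC, PTPRC, TREX1 and COL1A2 are members of the fixed lists. MUC13, a membrane mucin, rose by a log2 fold change of 2.43 (SE 0.108), the liver and gut transcription factor gene CREB3L3 by 1.96 (SE 0.144) and the Notch target HEY1 by 1.98 (SE 0.136). H19, the imprinted neighbour of IGF2 on chromosome 11, rose by 0.49 (SE 0.115), from 0.457% to 0.537% of counts in shControl to 0.724% to 0.768% in shRNH1. The glucose-responsive genes TXNIP (2.38, SE 0.111) and ARRDC4 (1.51, SE 0.253) rose, and MYC fell by 0.42 on the log2 scale (SE 0.1002). IFNL1, an interferon lambda gene, had 8, 12 and 15 counts in shControl and 44, 40 and 42 in shRNH1 (2.03, SE 0.379), while IFNB1 was listed at 0 in all 6 libraries. PTPRC, a leukocyte gene, had 0, 1 and 0 counts against 6, 8 and 11. The nuclease gene TREX1 and the collagen gene COL1A2 were listed at 0 in all 6 libraries, as were the mitochondrial genes, so these zeros need not mean absent RNA.

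Most targets of YAP and TEAD, transcriptional regulators that respond to cell shape and density, fell. Of 21 tested members 18 fell and 1, IGFBP3, rose, with a median log2 fold change of -0.77, and among them were CCN1, F3, ANKRD1 (-3.14), AMOTL2 (-1.80), NUAK2 (-1.21) and LATS2 (-1.10). Camera gave an unadjusted p = 7.22e-17, and an unadjusted p = 0.00569 with an estimated correlation. These are not on the scale of the adjusted p of the fixed lists. Without the members in lists fixed earlier or seen among the largest changes, 13 of 16 fell and 1 rose (unadjusted camera p = 9.10e-10, and p = 0.0101 with an estimated correlation). The list was chosen after CCN1 and F3 had been seen to fall in the same libraries. Its remaining members are therefore no independent test. Of 15 ERK output genes, which include negative feedback regulators, 13 fell and 0 rose, ETV4 (-0.82), DUSP6 (-0.56) and ETV5 (-0.50) among them. Of the 7 not seen earlier 6 fell (unadjusted camera p = 8.56e-08, and p = 0.0241 with an estimated correlation), with the same limit.

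For the rise of 35 of 44 interferon-stimulated genes, 3 technical explanations were tested. With all libraries thinned to the smallest total, 34 to 35 members stayed higher over 5 draws, which argues against the lower depth of the shRNH1 libraries. With an offset for GC content and length the median was 0.61 and 36 members were higher, which argues against such a trend. The summed CPM of leukocyte markers rose by 0.157% of the summed rise of the interferon list, which argues against immune cells in the shRNH1 cultures. A response to the loss of RNASEH1 and a response to the hairpin itself both stay open, and neither was tested because the labels give 1 knockdown group.

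For the fall of YAP/TEAD targets, the median of -0.81 with the GC content and length offset argues against such a trend. With the expression level offset 14 members were lower, against 18 without it. Of the fibroblast markers MFAP5 and PDGFRB fell with SPARC, yet the summed fall of COL1A1, COL1A2, COL3A1, DCN and LUM was -30.003% of the fall of SPARC, that is, a rise, which rests on COL1A1 because COL1A2 and DCN were listed at 0. The abundant fibroblast transcripts COL3A1 (0, 0 and 3 counts) and LUM (2, 0 and 0 counts) were almost missing from the shControl libraries, where SPARC measured 244 CPM, which argues against fibroblasts as the source of the SPARC lost. The tested ERK output genes, none of which is in the YAP/TEAD list used here, had a median of -0.56. Whether YAP/TEAD also regulates some of them was not tested. Of the ERK list 8 members had been seen earlier, so lower ERK output may go with the pattern only as far as the 7 tested members not seen earlier show it (median -0.50, unadjusted camera p = 0.0241 with an estimated correlation). Those 7 come from a list chosen after the same libraries had been seen, so they are no independent test. Which of the changes came first, and whether culture density differed between the groups, stays open and untested.

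For the fall of ribosome biogenesis and MYC targets, the median of -0.45 with the GC content and length offset, where 31 of 34 members were lower, argues against such a trend. The offset for expression level left a median of -0.28 with 18 members lower, against -0.43 and 27 without it. This lies between the bounds set before the value was seen, so the share of the fall that belongs to the general trend with expression level cannot be told apart from a change of these genes. MYC is itself a lower member of this list, so its fall is part of the same pattern and no separate evidence. A lower growth rate stays open and untested.

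Splits of the 6 libraries into 3 and 3 number 10, too few for a share below 0.1. The real split called 5424 genes by edgeR's test and the highest other 0, with at most 713 genes at an unadjusted p below the threshold, so 1 of 10 splits gave as many, and at an absolute log2 fold change of at least 1 it called 1234 against 0 (1 of 10). In the other splits the real difference lies within both sides and widens their spread. Few calls there follow from any strong difference between the groups, so these counts do not decide about chance. The 12 lists called by camera did not stand apart, since the highest other split called 16 and 3 of 10 splits, the real one included, called at least as many. Every other split joined libraries of both groups in unequal shares and so kept part of the real difference. Neither the list counts nor the medians are therefore compared with splits free of signal. Joining libraries of both groups makes a steady difference smaller in those splits. A larger median in the real split was thus favoured in advance and does not decide about chance. The cholesterol list (0.12 against 0.09 in the highest other split) and the fibroblast list (0.58 against 0.38), which camera did not call, also had their largest median there. The interferon list had an absolute median of 0.62 against 0.27 in the highest other split, ribosome biogenesis 0.43 against 0.18, and hypoxia and glycolysis 0.26 against 0.13. For the R-loop list (0.11 against 0.16), ribosomal proteins (0.08 against 0.14) and MHC class I (0.12 against 0.15) another split gave a larger median.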
